A study of Homo sapiens with 30 samples.

How the data were processed

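RNA abundance was measured in 30 libraries from 3 human breast cell lines edited at SF3B1, the gene for a core protein of the U2 spliceosome particle. T47D and MCF7 are oestrogen receptor positive breast cancer lines and MCF10A is a non-transformed breast epithelial line. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and ribosomal RNA was removed with the Illumina Ribo-Zero Plus kit before library preparation, and edited cells were grown like their parental line. Cutadapt 4.8, FastQC 0.12.1, STAR 2.7.11a and the build GRCh38.p13 are named in the submitters' processing notes, without their roles. The counter, the release of the gene annotation and whether strand was used are not given in the sources used here. Without strand, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as histone genes and the nuclear copies of mitochondrial genes, carry uncertain values.

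The authors deposited a table of raw counts per gene, in whole numbers, for 51802 annotated genes, of which 1998 had no count in any library. A second table deposited by the authors gives FPKM, that is counts scaled to the listed feature length and to the total counts over the listed genes. All 30 columns of each table were matched to samples by their names. Total counts ranged from 36075456 to 63173757 per library. Gene positions below are those listed in the authors' table and refer to GRCh38. The files hold gene totals, so splice junctions were not analysed here.

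Groups were taken from the labels. K700E, K666N, R625C and R625H name the amino acid changes at SF3B1. A PreCre library comes from the intermediate editing state with a selection cassette in an intron that disrupts the mutant allele, to an extent that may vary per the labels. Clones carry the name of the lineage they came from, and 2 MCF7 libraries come from cells that had reverted to the wild-type sequence. Clones of 1 lineage are not fully independent replicates, and nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these samples. In 19 pairs of libraries of 1 group, the chi-square of the counts per degree of freedom lay between 12.8 and 412, so no pair differed by as little as sampling noise.

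Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter with a minimum count of 10, robust dispersion estimates and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The T47D fit compared K700E with the parental and PreCre libraries together. The MCF7 fit had 5 levels, namely wild type (parental, unedited clone and reverted), PreCre, K700E, R625C and R625H. The MCF10A fit had 3 levels, with the parental and the K666N PreCre libraries as control. A fit of 17 libraries with a level for each line and genotype gave the mean K700E effect over the 3 lines and the test that the effects differ by line. Standard errors of log2 fold changes were taken as the absolute change divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to library size), with their SD over libraries.

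These tests, the gene lists, the rule for naming genes and the alternatives to be tried were fixed before the data were examined. The rule named SF3B1, then up to 5 protein-coding genes that rose and 5 that fell most among those with adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the libraries of both sides. For comparisons that are not of a mutation with its control, 3 genes each way were named. It added up to 4 called SF3B1 targets and up to 3 called members of each of 5 other lists with the smallest set p-values, or the member with the smallest p where none was called. Other genes named were chosen after their values were seen.

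The 21 lists were SF3B1 mis-spliced targets, U2 snRNP and branch point factors, nonsense-mediated decay factors, serine and one-carbon metabolism, amino acid stress response, haem and iron handling, mitochondrially encoded transcripts, nuclear oxidative phosphorylation, cell cycle and mitosis, replication-dependent histones, MYC targets and ribosome biogenesis, p53 targets, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, interferon response, NF-kappaB targets, oestrogen response, and luminal, basal and mesenchymal markers. They held from 13 to 69 genes. The target list shares 4 genes and the oestrogen list 5 genes with other lists. Each list was tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over all lists and comparisons, and again with the correlation estimated and with fry.

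Where all libraries of a group had 0 counts, the fold was set against a floor of 3 counts over the group. Where they had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Such intervals and floors cover counting error only, and the fitted folds of these genes are no bounds.

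Alternatives were RLE scaling, no low-count filter, a filter at 1 CPM, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1 and 0.1 (genes with FPKM of at least 1), other choices of control, fits of only the groups compared, a fold threshold of 2, each library left out in turn, each line left out, and each mutant against the PreCre clones of its own lineage with the lineage as a block. Lineage names come from the labels. Deviations from group means correlated between 0.272 and 0.510 in 7 MCF7 pairs of mutant and PreCre libraries of 1 lineage, and between -0.271 and 0.253 in other pairs. In T47D the 4 same-lineage pairs lay between -0.08 and 0.38. Added after the data were seen were counts without chromosome segments that stand apart, without both reverted libraries, and without K666N replicates 1 and 2. Segments were bins of 20 Mb whose median log2 change lay at least 0.4 from the median of the genes examined.

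The procedure was tested on simulated counts with 200 changed genes per comparison. At a 2-fold change 55.2% were recovered in the T47D comparison, 28.4% for MCF7 K700E, 55.2% for R625C, 43.3% for R625H, 56.7% for PreCre and 68.7% for the mean over 3 lines. For MCF10A K700E and K666N against control 1.49% were recovered at 2-fold, and 18.2% and 42.4% at 4-fold, and for K666N against K700E 0% at 2-fold and 31.8% at 4-fold. From 0 to 11 unchanged genes were called per comparison. Their share was highest for MCF10A K700E (3 of 16 calls) and T47D (11 of 108), and elsewhere ran from 0 of 29 to 5 of 91. The simulated libraries were independent, unlike clones of 1 lineage.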

Results

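RNA sequencing of ribosome-depleted total RNA gave gene counts for 30 libraries of isogenic breast cell lines with and without 1 of 4 point mutations of SF3B1, a U2 spliceosome protein that is recurrently mutated in cancer. T47D was represented by 1 parental library, 2 K700E PreCre clones and 4 K700E clones. MCF7 had 1 parental library, 1 unedited clone, 2 reverted clones, both derived from the clone of K700E replicate 1 per the labels, 5 PreCre clones, 2 K700E, 3 R625C and 2 R625H clones. In MCF10A there were 1 parental library, 1 K666N PreCre library, 2 K700E and 3 K666N libraries, the last numbered 1, 2 and 5. Per the labels, the T47D and MCF10A mutants were heterozygous and the MCF7 mutants carried a variable share of the mutant allele. Total counts per library ranged from 36075456 to 48543025 in T47D, 42924811 to 62477814 in MCF7 and 42645396 to 63173757 in MCF10A.

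The edited gene itself, SF3B1 (chromosome 2, positions 197388515 to 197435079), was expressed in every library. In T47D it stood at 299 ± 17.1 CPM (SD, n = 4) in K700E cells, 313 in the parental library and 196 ± 15.5 (SD, n = 2) in PreCre clones. MCF7 wild-type libraries had 485 ± 28.0 CPM (SD, n = 4), K700E 521 ± 60.4 (SD, n = 2), R625C 476 ± 28.3 (SD, n = 3), R625H 389 ± 29.0 (SD, n = 2) and PreCre clones 348 ± 35.5 (SD, n = 5). For MCF10A the values were 444 in the parental library, 254 in PreCre, 418 ± 16.2 (SD, n = 2) in K700E and 298 ± 50.4 (SD, n = 3) in K666N. No mutant differed from its control at SF3B1 in edgeR's quasi-likelihood test (adjusted p from 0.234 to 1). PreCre clones of MCF7 were lower than wild type by a log2 change of -0.48 (SE 0.10, edgeR adjusted p = 0.0110). Gene totals do not separate the alleles.

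The first comparison asked what K700E changed in T47D, with 4 K700E against 3 control libraries. EPGN, a ligand of the epidermal growth factor receptor, rose by 4.27 log2 units (SE 0.42) and ETV5, a transcription factor of the ETS family, by 4.21 (SE 0.43). TGM2, a protein-crosslinking transglutaminase, rose by 4.02 (SE 0.35), UCHL1, a ubiquitin hydrolase, by 3.12 (SE 0.30) and ANXA1, a phospholipid-binding annexin, by 3.05 (SE 0.66). SOX2, a stem cell transcription factor, fell by 6.14 (SE 0.99) and FOXJ1, a regulator of motile cilia, fell by 6.01 (SE 1.26). CHST1, a sulfotransferase, fell by 5.87 (SE 1.28), the homeobox gene CUX2 fell by 5.46 (SE 0.65) and ADCY2, an adenylyl cyclase, fell by 5.01 (SE 0.89). The edgeR adjusted p of these 10 genes lay between 0.00109 and 0.0408. The control libraries themselves differed in SOX2 and FOXJ1, with 1.60 and 1.37 CPM in the parental library against 19.4 and 24.3 and 29.4 and 73.0 in the PreCre clones.

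Of 29 measured genes known to be mis-spliced in SF3B1-mutant cells, 0 rose and 8 fell in T47D K700E, and 1 rose and 8 fell when adjusted over the list alone. PPP2R5A, a regulatory subunit of protein phosphatase 2A (chromosome 1, positions 212285410 to 212361853), fell by 1.41 (SE 0.10, edgeR adjusted p = 0.000309). ABCB7, a mitochondrial transporter needed for iron-sulfur proteins, fell by 1.49 (SE 0.12). TTI1, a partner of kinases of the PI3K-related family (chromosome 20, positions 37983007 to 38033461), fell by 1.30 (SE 0.11) and the haem synthesis enzyme PPOX fell by 1.05 (SE 0.11). The median of the list was -0.18, with a camera adjusted p of 5.19e-07 and an adjusted p = 0.20 with an estimated correlation. Amino acid stress genes included 4 that rose of 25 (8 adjusted over the list alone), among them CHAC1, which degrades glutathione, at 1.74 (SE 0.29), the amino acid transporter SLC7A1 at 0.65 (SE 0.14) and the mTOR inhibitor DDIT4 at 0.99 (SE 0.21). Their median was 0.51 (camera adjusted p = 1.06e-07, adjusted p = 0.62 with an estimated correlation).

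Oestrogen response genes went both ways in T47D K700E, with 4 that rose and 11 that fell of 30 (6 and 12 adjusted over the list alone). PRLR, the prolactin receptor, fell by 1.76 (SE 0.16) and the retinoic acid receptor RARA fell by 0.66 (SE 0.09), while AREG, a growth factor, rose by 2.37 (SE 0.24). The median was -0.38 with a camera adjusted p of 0.00364 and an adjusted p = 0.595 with an estimated correlation. Among 18 luminal markers 4 fell and 0 rose (6 fell and 1 rose adjusted over the list alone), including FOXA1 at -0.74 (SE 0.12), MUC1 at -0.73 (SE 0.14) and ESR1, the oestrogen receptor, at -0.83 (SE 0.20). Their median was -0.35 (camera adjusted p = 0.0103, adjusted p = 0.688 with an estimated correlation), and it was 0.01 against the parental library alone. None of 26 interferon response genes was called, over all genes or adjusted over the list alone, and USP18 had 0.84 (SE 0.23, edgeR adjusted p = 0.0551). The median of that list was 0.84 (camera adjusted p = 0.000337, adjusted p = 0.733 with an estimated correlation). Mitochondrially encoded transcripts included 2 that rose of 13 (3 adjusted over the list alone), MT-ND6 at 0.78 (SE 0.18) and MT-ND3 at 0.61 (SE 0.15), with a median of 0.18 (camera adjusted p = 0.0162, adjusted p = 0.731 with an estimated correlation).

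In all, edgeR called 2166 of 24420 genes in T47D K700E, 933 higher and 1233 lower, and 988 changed at least 2-fold. With limma on log2 FPKM, 821 of 1432 called genes (pseudocount 0.1) and 841 of 1480 (pseudocount 1) were higher. The count was 758 without PreCre replicate 1, 1242 without PreCre replicate 2, 948 without K700E replicate 1, 716 without K700E replicate 3 and 3327 without the parental library. Against the PreCre clones with the lineage as a block it was 3369.

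K700E in MCF7 was compared with wild type in 2 against 4 libraries. ASTL, a secreted metalloprotease, rose by 5.16 (SE 0.77), SPRY4, an inhibitor of receptor tyrosine kinase signalling, by 4.92 (SE 0.88) and GPRIN3, a G protein regulator, by 4.79 (SE 0.70). The transcription factors ATOH8 and DLX2 rose by 4.72 (SE 1.01) and 4.66 (SE 0.99). NR2F1, an orphan nuclear receptor, fell by 6.07 (SE 1.03), the zinc finger gene PLAGL1 fell by 3.95 (SE 0.64) and the ubiquitin ligase gene NEURL1 fell by 3.30 (SE 0.61). DACH1, a transcriptional corepressor, fell by 2.86 (SE 0.60) and A4GALT, the synthase of the glycolipid Gb3, fell by 2.62 (SE 0.62). The edgeR adjusted p of these genes lay between 0.00387 and 0.0364. SPRY4 had 29.4 CPM in K700E replicate 1 and 2.13 in replicate 2, against 0.440 to 0.665 in wild-type libraries.

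Replication-dependent histones were the list with the smallest camera p in MCF7 K700E, with 23 of 27 genes that fell and 0 that rose (25 fell adjusted over the list alone). H3C8 fell by 1.16 (SE 0.17), H3C12 fell by 1.54 (SE 0.24) and H2AC14 fell by 1.22 (SE 0.20), and the list's median was -1.02 (camera adjusted p = 3.49e-34, adjusted p = 0.202 with an estimated correlation). Of the 13 mitochondrially encoded transcripts 9 rose (13 adjusted over the list alone), with MT-ND5 at 2.02 (SE 0.28), MT-CO2 at 1.42 (SE 0.22) and MT-ND4L at 1.59 (SE 0.25). Their median was 1.26 (camera adjusted p = 1.84e-23, adjusted p = 0.202 with an estimated correlation). These transcripts took 3.27% and 1.75% of counts in the K700E libraries, 1.39% and 1.58% in the parental library and the unedited clone, and 0.717% and 0.708% in the reverted clones, which also had the fewest detected genes in MCF7 (30393 and 29320).

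Among 34 cell cycle genes in MCF7 K700E 8 fell and 0 rose (24 fell adjusted over the list alone), including the replication licensing factors CDC6 at -0.81 (SE 0.16) and MCM2 at -0.67 (SE 0.17) and the replication clamp PCNA at -0.69 (SE 0.16). The list's median of -0.51 (camera adjusted p = 1.90e-16, adjusted p = 0.290 with an estimated correlation) became 0.07 against the PreCre clones of the same lineages. Amino acid stress genes included 10 of 24 that rose (15 adjusted over the list alone), with the transaminase GPT2 at 1.28 (SE 0.19), asparagine synthetase ASNS at 1.70 (SE 0.30) and CHAC1 at 3.44 (SE 0.59). That list's median was 0.97 (camera adjusted p = 2.85e-13, adjusted p = 0.448 with an estimated correlation). Of 22 cholesterol synthesis genes 1 fell, LSS, which makes lanosterol, at -0.81 (SE 0.20), and 12 fell adjusted over the list alone, with a median of -0.50 (camera adjusted p = 9.04e-09, adjusted p = 0.353 with an estimated correlation). SF3B1 targets included 2 that rose and 4 that fell of 29 (2 and 6 adjusted over the list alone). TTI1 fell by 0.94 (SE 0.15), PPP2R5A fell by 0.86 (SE 0.19) and MAP3K7, a kinase of inflammatory signalling, fell by 0.58 (SE 0.14), while the transporter gene ABCC5 rose by 0.83 (SE 0.18). The target list's median was -0.16 (camera adjusted p = 0.00610, adjusted p = 0.574 with an estimated correlation). With the lineage as a block that median was -0.075, with a reversed test direction.

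edgeR called 909 of 24985 genes in MCF7 K700E, 585 higher and 324 lower, and 484 at least 2-fold. On log2 FPKM, limma placed 487 of 1110 (pseudocount 0.1) and 510 of 1104 (pseudocount 1) on the higher side. The count was 436 without K700E replicate 1, 2015 without K700E replicate 2 and 402 without reverted replicate 1. It was 221 against PreCre with the lineage as a block and 0 in a fit of only the K700E and wild-type libraries. Of the 324 lower genes 51 lie on chromosome 6, which holds most histone genes, against 16.2 by its share of tested genes, and 14 on chromosome 21 against 3.80.

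**Figure D1:**
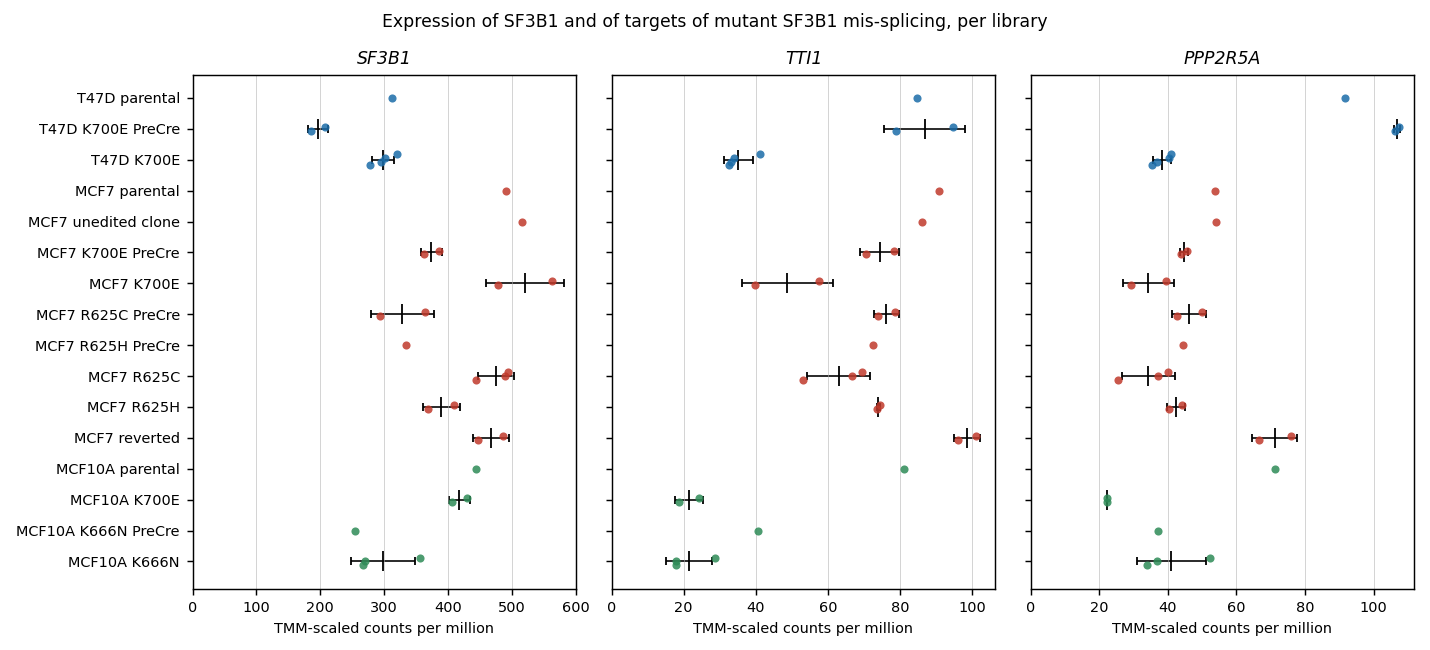
TMM-scaled CPM (x axis) of SF3B1, TTI1 and PPP2R5A in each group of libraries (y axis), where dots are libraries, the black tick and bar are the mean and SD of groups with more than 1 library, and colours mark the cell line. TTI1 lay between 32.4 and 41.2 in T47D K700E against 78.9 to 94.8 in T47D controls, and at 24.3 and 18.7 in MCF10A K700E against 81.2 and 40.6 in the parental and PreCre libraries.

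R625C, a change at another hotspot residue, was compared with wild type in 3 against 4 MCF7 libraries. SLFN5, a member of the schlafen family, rose by 1.87 (SE 0.28) and the autophagy gene GABARAPL1 by 1.41 (SE 0.27). OSGIN1, a stress-induced growth inhibitor, rose by 1.41 (SE 0.26), the mTOR-binding protein gene DEPTOR by 1.35 (SE 0.25) and SDC2, a cell surface proteoglycan, by 1.19 (SE 0.21). NR2F1 fell by 6.56 (SE 0.88), LINGO1, a membrane protein of neurons, fell by 2.15 (SE 0.37) and TPP2, a cytosolic peptidase (chromosome 13, positions 102596986 to 102679958), fell by 1.93 (SE 0.30). PLBD1, a phospholipase-like gene, fell by 1.86 (SE 0.35) and the small GTPase gene DIRAS1 fell by 1.83 (SE 0.30). The edgeR adjusted p of these genes lay between 0.0362 and 0.0477. The 57 genes of chromosome 13 beyond 80 Mb, near TPP2, had medians of -1.04 to -0.94 in the R625C clones relative to unedited cells, and TPP2 less the median of its 20 Mb bin was -1.22, -0.68 and -0.39 in these clones against -0.21 and -0.23 in their PreCre clones. GABARAPL1 had -0.34 against PreCre clones with the lineage as a block and -0.56 against all PreCre clones.

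PPP2R5A, at -0.87 (SE 0.16, edgeR adjusted p = 0.0477), was the 1 called gene of 29 SF3B1 targets in R625C, and 8 fell adjusted over the list alone. The list's median was -0.20 (camera adjusted p = 3.84e-06, adjusted p = 0.274 with an estimated correlation). None of 13 mitochondrially encoded transcripts was called over all genes and 11 rose adjusted over the list alone, with MT-ND3 at 0.72 (SE 0.16, edgeR adjusted p = 0.0831) and a median of 0.69 (camera adjusted p = 1.29e-10, adjusted p = 0.490 with an estimated correlation). No cell cycle gene was called of 34 (0 adjusted over the list alone). BUB1, a mitotic checkpoint kinase, had -0.52 (SE 0.16), and the list's median of -0.24 (camera adjusted p = 0.000205, adjusted p = 0.670 with an estimated correlation) was 0.26 in the lineage block. For the 28 MYC targets 0 were called and 2 fell adjusted over the list alone, NOP58 had -0.55 (SE 0.14), and the median of -0.16 (camera adjusted p = 0.000517, adjusted p = 0.703 with an estimated correlation) was 0.22 in the block. Of 27 histone genes 0 were called (0 adjusted over the list alone), H2BC5 had -0.44 (SE 0.15), and the median of -0.22 (camera adjusted p = 0.00347, adjusted p = 0.731 with an estimated correlation) was 0.53 in the block. ZMAT3, the p53 target with the smallest p, had 0.78 (SE 0.23, edgeR adjusted p = 0.145).

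edgeR called 41 genes in R625C, 18 higher and 23 lower, where limma on log2 FPKM gave 10 of 27 (pseudocount 0.1) and 18 of 39 (pseudocount 1) higher and DESeq2 238 of 767. The count was 0 without R625C replicate 1, without reverted replicate 1 or without reverted replicate 2, 1 without R625C replicate 3, 11 without R625C replicate 2, 191 without the parental library and 142 without the unedited clone. It was 0 against PreCre with the lineage as a block.

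R625H, another change at the same residue, was compared with wild type in 2 against 4 libraries. ABCC2, a drug transporter, rose by 1.88 (SE 0.34), GABARAPL1 by 1.59 (SE 0.29) and the zinc finger repressor ZBTB20 by 1.57 (SE 0.28). TDRD1, a Tudor-domain gene of the germline, had 1 count in both R625H libraries together against 14492 in wild type, a ratio of 8796 (95% counting interval 1579 to 3.48e+05), and 2.47 CPM in the R625H PreCre clone. PCSK1N, an inhibitor of a prohormone convertase, was at least 462-fold lower. GABPB1, a subunit of an ETS-family factor, fell by 1.87 (SE 0.32), the glycosyltransferase gene POGLUT3 fell by 1.44 (SE 0.22) and IGFBP2, which binds insulin-like growth factors, fell by 1.37 (SE 0.22). The edgeR adjusted p of these 8 genes lay between 0.0311 and 0.0492. GABARAPL1 had -0.11 in the lineage block and -0.37 against all PreCre clones.

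None of the 27 listed histone genes was called in R625H, and 25 fell adjusted over the list alone. H2BC8, a histone gene outside the list, was called at -0.94 (SE 0.17, edgeR adjusted p = 0.0492). H2BC11 had -0.95 (SE 0.20, edgeR adjusted p = 0.0846) and the list's median was -0.75 (camera adjusted p = 1.27e-29, adjusted p = 0.202 with an estimated correlation). Of 34 cell cycle genes 0 were called and 7 fell adjusted over the list alone, with the thymidine kinase gene TK1 at -0.57 (SE 0.14). Their median of -0.35 (camera adjusted p = 3.37e-10, adjusted p = 0.501 with an estimated correlation) was 0.11 in the lineage block. Among 69 nuclear genes of oxidative phosphorylation 1 fell (2 adjusted over the list alone), NDUFB1 of respiratory complex I at -0.74 (SE 0.13), and the median of -0.29 (camera adjusted p = 1.08e-09, adjusted p = 0.620 with an estimated correlation) was 0.13 in the block. Of 28 MYC targets 0 were called and 4 fell adjusted over the list alone, with nucleolin NCL at -0.68 (SE 0.14) and a median of -0.32 (camera adjusted p = 1.34e-06, adjusted p = 0.620 with an estimated correlation), which was 0.12 in the block. DLST of the oxoglutarate dehydrogenase complex, at -0.65 (SE 0.10), was the 1 called gene of 29 SF3B1 targets, of which 5 fell adjusted over the list alone. The target list's median was -0.30 (camera adjusted p = 4.90e-05, adjusted p = 0.353 with an estimated correlation). MT-ATP6 had 0.50 (SE 0.26, edgeR adjusted p = 0.423).

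edgeR called 27 genes in R625H, 8 higher and 19 lower, against 1 of 37 (pseudocount 0.1) and 3 of 37 (pseudocount 1) higher with limma on log2 FPKM. The count was 0 without R625H replicate 1, without reverted replicate 1 or without reverted replicate 2, 9 without R625H replicate 2, 95 without the parental library and 184 without the unedited clone, and 2 in the lineage block. Of the 19 lower genes 9 lie on chromosome 14, DLST and NDUFB1 among them, where 0.627 would by its share of tested genes, and 4 lie on chromosome 2 beyond 200 Mb, IGFBP2 among them. Relative to unedited cells, genes of chromosome 14 had a median of -0.285 and -0.308 in the R625H clones and 0.011 in their PreCre clone, and those of the chromosome 2 region -0.30 and -0.31 against 0.032.

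The intermediate PreCre state was set against wild type in 5 against 4 MCF7 libraries. ZNF716, a zinc finger gene, had a fitted change of 8.12 (SE 2.04), with 17.1 and 15.2 CPM in the R625C PreCre clones. PSG4, a glycoprotein gene of the placenta, rose by 3.85 (SE 1.08) and GPRIN3 by 3.80 (SE 0.62). The zinc finger gene ZNF385B fell by 4.22 (SE 0.86), PGR, the progesterone receptor, fell by 3.62 (SE 0.78) and the secreted glycoprotein gene LRG1 fell by 3.38 (SE 0.63), with edgeR adjusted p from 0.00591 to 0.0470 for these 6 genes. Of 27 histone genes 24 fell (25 adjusted over the list alone), H1-3 at -1.19 (SE 0.18) and H3C8 at -0.79 (SE 0.12) among them, with a median of -0.70 (camera adjusted p = 9.70e-27, adjusted p = 0.241 with an estimated correlation). Of 34 cell cycle genes 19 fell (25 adjusted over the list alone), including the mitotic kinases BUB1B at -0.70 (SE 0.10) and AURKB at -0.74 (SE 0.12), with a median of -0.50 (camera adjusted p = 1.63e-19, adjusted p = 0.241 with an estimated correlation). Of 69 nuclear genes of oxidative phosphorylation 25 fell (41 fell and 1 rose adjusted over the list alone), with the ATP synthase gene ATP5MC2 at -0.63 (SE 0.09) and a median of -0.34 (camera adjusted p = 2.28e-16, adjusted p = 0.517 with an estimated correlation). SF3B1 targets included 1 that rose, ABCC5 at 0.64 (SE 0.14), and 2 that fell of 29, SERBP1 at -0.47 (SE 0.12) and RPL31 at -0.51 (SE 0.14). Adjusted over the list alone 3 rose and 8 fell, and the median was -0.22 (camera adjusted p = 0.00685, adjusted p = 0.595 with an estimated correlation).

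edgeR called 2098 genes in PreCre clones, 703 higher and 1395 lower, but limma on log2 FPKM gave 1097 of 1522 (pseudocount 0.1) and 1101 of 1523 (pseudocount 1) higher. On that scale the median over the 14939 genes in both tests lay 0.21 and 0.18 higher than in edgeR. The count was 377 without reverted replicate 1, 370 without reverted replicate 2, 20 without both, 4470 without the unedited clone, 1310 without R625C PreCre replicate 1, 514 without R625C PreCre replicate 2 and 1031 without the R625H PreCre clone.

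The hotspots were compared directly in MCF7, with the mean of R625C (3 libraries) and R625H (2 libraries) against K700E (2 libraries). PLAGL1 was higher in the R625 mutants by 3.93 (SE 0.64), SKIDA1 by 2.39 (SE 0.55) and DACH1 by 2.21 (SE 0.58). ASTL was lower at -4.41 (SE 0.70), the ankyrin repeat gene SOWAHA at -4.40 (SE 0.70) and GRHL3, an epithelial transcription factor, at -4.26 (SE 0.96), with an edgeR adjusted p of at most 0.0485. Of 24 amino acid stress genes 8 were lower (17 adjusted over the list alone), with GPT2 at -1.37 (SE 0.18) and CHAC1 at -2.45 (SE 0.55) and a median of -0.78 (camera adjusted p = 3.91e-11, adjusted p = 0.501 with an estimated correlation). Of 27 histone genes 3 were higher (15 adjusted over the list alone), H2AC14 at 0.99 (SE 0.19) among them, with a median of 0.50 (camera adjusted p = 8.92e-10, adjusted p = 0.557 with an estimated correlation). Mitochondrially encoded transcripts included 6 of 13 that were lower (7 adjusted over the list alone), MT-ND5 at -1.47 (SE 0.27) among them, with a median of -0.82 (camera adjusted p = 4.24e-08, adjusted p = 0.557 with an estimated correlation). edgeR called 778 genes, 144 higher and 634 lower, where limma on log2 FPKM gave 459 of 802 (pseudocount 0.1) and 393 of 732 (pseudocount 1) higher. The count was 321 without K700E replicate 1, 2019 without K700E replicate 2, 287 without R625C replicate 2, 368 without R625C replicate 3, 213 without R625H replicate 1 and 17 without R625H replicate 2. In a fit of only these 3 groups it was 116. Of the 634 lower genes 64 lie on chromosome 14, against 20.9 by its share of tested genes, and of the 144 higher genes 12 lie on chromosome 13 (2.76) and 11 on chromosome 21 (1.69).

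Reverted MCF7 clones were compared with the never-edited parental library and unedited clone, 2 against 2 libraries. ANKRD1, a target of YAP signalling, was higher by 5.86 (SE 1.27), the cytokine gene IL24 by 5.48 (SE 1.19) and the membrane protein gene TM4SF1 by 5.16 (SE 1.03). SLC24A3, a sodium-calcium exchanger, was at least 304-fold lower, the zinc finger gene ZNF354C at least 178-fold and the GTPase gene ARL11 at least 82.8-fold (edgeR adjusted p of the 6 genes from 2.93e-05 to 0.0177). Of 27 histone genes 16 were higher (23 adjusted over the list alone), with H3C10 at 0.79 (SE 0.13) and a median of 0.61 (camera adjusted p = 1.82e-13, adjusted p = 0.324 with an estimated correlation). Of 26 hypoxia and glycolysis genes 11 were higher (18 adjusted over the list alone), including LDHA at 0.85 (SE 0.13) and P4HA1 at 0.84 (SE 0.14), with a median of 0.64 (camera adjusted p = 2.03e-10, adjusted p = 0.202 with an estimated correlation). Among 28 MYC targets 10 were higher (18 adjusted over the list alone), with the ornithine decarboxylase gene ODC1 at 1.04 (SE 0.19) and a median of 0.44 (camera adjusted p = 3.11e-08, adjusted p = 0.517 with an estimated correlation). SF3B1 targets included 4 of 29 that were higher (6 adjusted over the list alone), DPH5 at 0.56 (SE 0.17) and DVL2 at 0.43 (SE 0.13) among them, with a median of 0.30 (camera adjusted p = 0.00603, adjusted p = 0.324 with an estimated correlation). edgeR called 3218 genes, 1518 higher and 1700 lower, where limma on log2 FPKM gave 464 of 1979 (pseudocount 0.1) and 400 of 1345 (pseudocount 1) higher, with a median over the 14939 genes in both tests that was 0.23 and 0.20 lower than in edgeR. The count was 1935 without the parental library, 100 without the unedited clone, 318 without reverted replicate 1 and 269 without reverted replicate 2.

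K700E in MCF10A was compared with control in 2 against 2 libraries. KRT14, a keratin of basal epithelium, rose by 4.34 (SE 0.55, edgeR adjusted p = 0.0449), with 33.9 and 32.6 CPM against 2.49 in the parental library and 0.782 in the PreCre library. The transcription factor ONECUT2 was at least 314-fold higher, with 888 counts against 0, and the epoxide hydrolase gene EPHX4 had a ratio of 886 (836 counts against 1, 95% counting interval 159 to 3.50e+04). H3C7, a histone H3 gene, was at least 3338-fold lower and the linker histone gene H1-3 at least 2534-fold. H2BC9, a histone H2B gene, had 2 counts against 11576, a ratio of 5461 (95% counting interval 1512 to 4.51e+04). WT1, a zinc finger transcription factor, was at least 307-fold lower and MTARC2, a mitochondrial reductase gene, at least 253-fold. The edgeR adjusted p of these genes lay between 0.00467 and 0.0484.

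The 3 histone genes lie side by side with H3C6 on chromosome 6 between positions 26224199 and 26253710, and no K700E library had more than 2 counts in any of the 4. The flanking genes H2AC8 and H3C8 stood at 93.3% and 101% of the mean of the controls in the lower K700E library for each. The controls differed, with 165 and 58.1 CPM for H2AC8 and 180 and 34.5 for H3C8 in the parental and PreCre libraries. The K700E libraries had 104 and 112 CPM for H2AC8 and 123 and 109 for H3C8. Of 26 measured histone genes 3 fell (3 adjusted over the list alone), and the median of the other 23 was -0.05 (range -0.71 to 4.43). The list's median was -0.13, also with the 3 genes at their bounds, against a mean of -1.50 (camera adjusted p = 0.000139, adjusted p = 0.731 with an estimated correlation). Against the PreCre library alone the list's median was 0.52, with a reversed test direction.

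**Figure D2:**
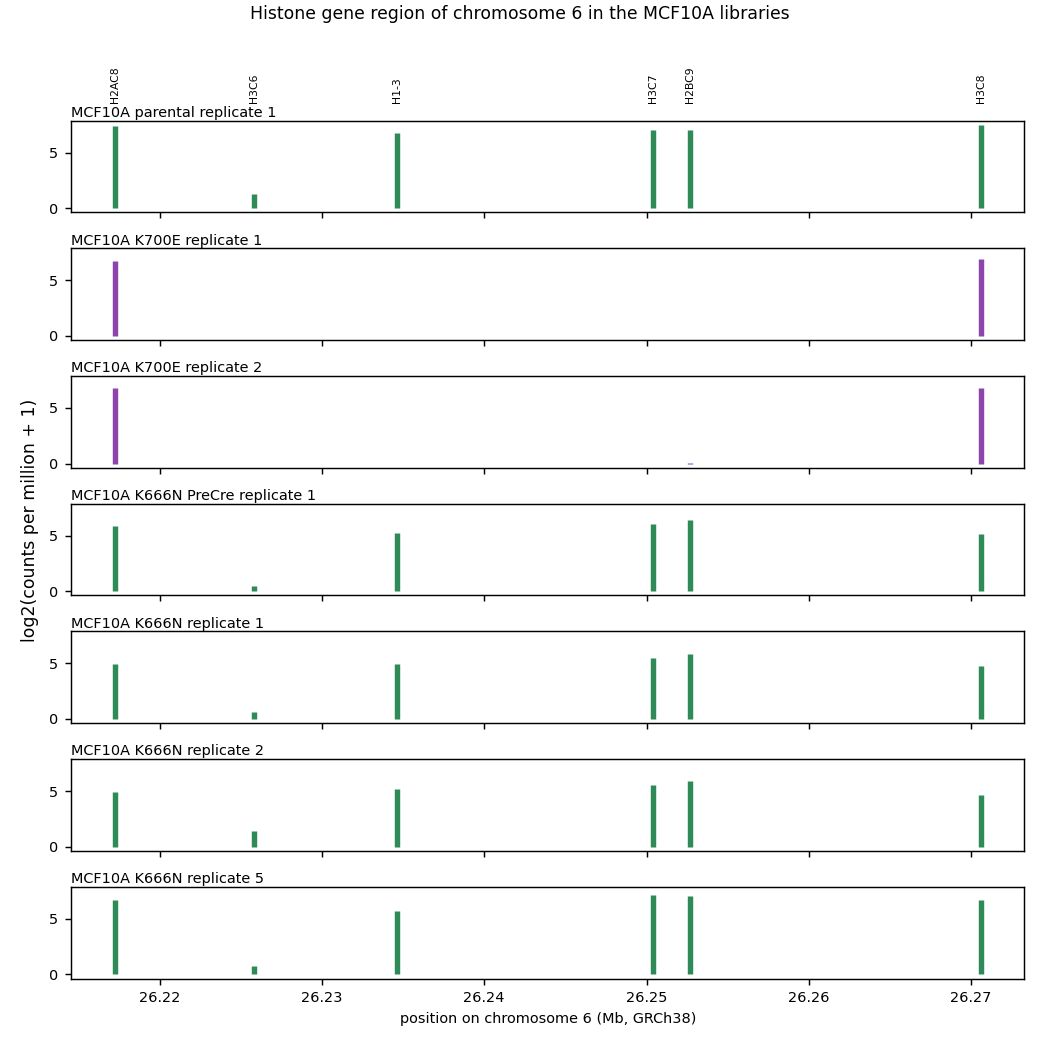
Expression as log2(CPM + 1) (y axis) of the genes with at least 20 counts in some library across the histone cluster of chromosome 6 (x axis, GRCh38 position), with 1 panel per MCF10A library, bars of fixed width at gene midpoints, purple for K700E and green for the other libraries. The K700E panels lack signal from 26224199 to 26253710, where the highest count was 2, and keep H2AC8 and H3C8 on either side.

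None of 29 SF3B1 targets was called over all genes in MCF10A K700E, and 7 fell adjusted over the list alone, BRD9 at -1.80, TTI1 at -1.50, DPH5 at -1.44, ABCB7 at -1.29, PPP2R5A at -1.28, MAP3K7 at -1.18 and DLST at -0.93. BRD9, a chromatin remodelling gene, had an edgeR adjusted p of 0.0511 over all genes and lies on chromosome 5 (positions 850291 to 892801), whose first 20 Mb had a median of -0.89 in both K700E libraries relative to the parental library. The list's median was -0.16 (camera adjusted p = 0.00166, adjusted p = 0.517 with an estimated correlation). Of 13 mitochondrially encoded transcripts 0 were called over all genes and 8 rose adjusted over the list alone, with MT-ND6 at 1.23 (SE 0.23, edgeR adjusted p = 0.169) and a median of 0.86 (camera adjusted p = 9.41e-14, adjusted p = 0.241 with an estimated correlation). No interferon response gene was called of 24 (0 adjusted over the list alone), with IFIT1 at 1.23 (SE 0.52) and a median of 0.59 (camera adjusted p = 1.22e-06, adjusted p = 0.555 with an estimated correlation). Of 21 NF-kappaB targets 0 were called (0 adjusted over the list alone), with CD83 at 1.06 (SE 0.34) and a median of 0.68 (camera adjusted p = 2.67e-06, adjusted p = 0.620 with an estimated correlation). KRT14 was the 1 of 20 basal markers that rose (1 adjusted over the list alone, median 0.17, camera adjusted p = 0.0292, adjusted p = 0.490 with an estimated correlation). The hypoxia gene NDRG1 had 1.10 (SE 0.26, edgeR adjusted p = 0.357).

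edgeR called 34 of 22693 genes in MCF10A K700E, 3 higher and 31 lower, limma on log2 FPKM 1 of 12 (pseudocount 0.1) and 3 of 14 (pseudocount 1) higher, and DESeq2 87 of 281. The count was 0 without K700E replicate 1, 13 without K700E replicate 2 and 0 in a fit of only K700E and control.

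K666N in MCF10A was compared with control in 3 against 2 libraries, and edgeR called 0 of 22693 genes. An unadjusted p under 0.05 was found for 856, fewer than unchanged genes alone would give. DESeq2 called 97 and limma 0, and edgeR called 2 genes without the PreCre library. Mitochondrially encoded transcripts had the largest list median at 1.85, with 0 of 13 called over all genes and 11 that rose adjusted over the list alone (camera adjusted p = 3.49e-74, adjusted p = 0.135 with an estimated correlation). MT-ND6, a subunit of complex I, had 2.13 (SE 0.23, edgeR adjusted p = 0.207). These transcripts took 2.35 to 2.59% of counts in K666N libraries against 0.796% in the parental and 0.890% in the PreCre library. Among 29 SF3B1 targets 0 were called over all genes and 3 fell adjusted over the list alone, ABCB7 at -1.22, DPH5 at -1.26 and TTI1 at -1.51, with a median of -0.14 (camera adjusted p = 0.000943, adjusted p = 0.517 with an estimated correlation). TTI1 had 17.7, 17.8 and 28.8 CPM in K666N libraries.

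Histone genes, MYC targets, basal markers and nuclear oxidative phosphorylation had 0 called members in K666N over all genes and 0 adjusted over the list alone. The 26 histone genes had a median of -0.94 (camera adjusted p = 3.92e-13, adjusted p = 0.611 with an estimated correlation), and H3C12 had -3.56 (SE 1.31) but 3.09 against the PreCre library alone. The 28 MYC targets had a median of -0.48 (camera adjusted p = 7.86e-07, adjusted p = 0.670 with an estimated correlation), with the nucleolar gene NPM3 at -0.68 (SE 0.29). The 20 basal markers had 0.51 (camera adjusted p = 2.66e-06, adjusted p = 0.202 with an estimated correlation), with the laminin gene LAMA3 at 1.13 (SE 0.37). The 69 nuclear genes of oxidative phosphorylation had -0.23 (camera adjusted p = 7.46e-05, adjusted p = 0.733 with an estimated correlation) but 0.14 against the PreCre library alone, and COX7B had -0.47 (SE 0.23). The TMM scaling factor was 0.703 in K666N replicate 5 and 0.737 in the parental library, against 1.01 in the PreCre library, 0.987 in K666N replicate 1 and 0.960 in K666N replicate 2. Replicate 5 also stood apart in its counts, with a chi-square per degree of freedom of 356 and 412 from replicates 1 and 2. Between replicates 1 and 2 it was 25.7. The K666N medians here and in the comparison with K700E average over these unlike libraries.

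The direct comparison of K666N (3 libraries) with K700E (2 libraries) in MCF10A had H3C7 at least 2603-fold, H1-3 at least 1301-fold and the sodium channel subunit gene SCNN1B at least 319-fold higher in K666N. EPHX4 was at least 408-fold lower, ONECUT2 had a ratio of 650 (2 counts in K666N, 95% counting interval 180 to 5379) and the neuronal pentraxin gene NPTX1 a ratio of 534 (3 counts in K666N, interval 182 to 2592), and the edgeR adjusted p of these 6 genes lay between 0.00732 and 0.0334. Of 13 mitochondrially encoded transcripts 0 were called over all genes and 10 were higher adjusted over the list alone, with MT-ND1 at 1.27 (SE 0.24) and a median of 0.99 (camera adjusted p = 9.49e-13, adjusted p = 0.257 with an estimated correlation). Cell cycle genes had 0 of 34 called (0 adjusted over the list alone) and a median of -0.52 (camera adjusted p = 1.12e-05, adjusted p = 0.731 with an estimated correlation). Nuclear oxidative phosphorylation genes had 0 of 69 called (0 adjusted over the list alone) and a median of -0.36 (camera adjusted p = 0.000120, adjusted p = 0.738 with an estimated correlation). Of 26 histone genes 3 were higher (3 higher and 1 lower adjusted over the list alone), with a median of -0.78, a mean of 0.55 and a test direction of down (camera adjusted p = 0.137). edgeR called 76 genes, 52 higher and 24 lower, limma on log2 FPKM 22 of 27 (pseudocount 0.1) and 17 of 23 (pseudocount 1) higher, and DESeq2 535 genes. The count was 4 without K700E replicate 1, 13 without K700E replicate 2, 31 without K666N replicate 1, 29 without K666N replicate 2, 145 without K666N replicate 5 and 9 without K666N replicates 1 and 2 together.

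The average change under K700E was estimated as the mean of the effects in the 3 lines, from 8 K700E and 9 control libraries. SOCS3, a feedback inhibitor of cytokine signalling, rose by 1.62 (SE 0.20), TRANK1 by 1.51 (SE 0.21) and MT-ND6 by 1.46 (SE 0.23). GBP3, an interferon-induced GTPase gene, rose by 1.35 (SE 0.29) and GULP1, an adaptor of engulfment, by 1.33 (SE 0.23). MAP2K6, a kinase upstream of p38, fell by 2.52 (SE 0.41), CHDH, choline dehydrogenase, fell by 2.10 (SE 0.18) and A4GALT fell by 1.70 (SE 0.17). RDX, which links actin to the membrane, fell by 1.59 (SE 0.20) and the endoplasmic reticulum cochaperone DNAJC3 fell by 1.37 (SE 0.14). The edgeR adjusted p of these genes lay between 8.67e-06 and 0.0270. CHDH had -0.76 in T47D, -0.56 in MCF7 and -4.95 in MCF10A, and these effects differed between the lines (edgeR adjusted p = 0.000137). MAP2K6 had -3.23 in T47D and -0.68 in MCF7 and was too low for the MCF10A fit, with 0 and 1 counts in K700E against 14 and 2 in controls. DNAJC3 (chromosome 13, positions 95677139 to 95794988) had -1.02, -0.92 and -2.17 in T47D, MCF7 and MCF10A, and genes of chromosome 13 beyond 80 Mb had a median of -0.86 in MCF7 K700E replicate 2 and medians of -0.60 to -0.47 in the MCF10A K700E libraries.

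Of 29 SF3B1 targets 7 fell and 0 rose in the mean K700E effect (8 fell adjusted over the list alone). TTI1 fell by 1.25 (SE 0.15), ABCB7 fell by 1.24 (SE 0.15), PPP2R5A fell by 1.19 (SE 0.14) and MAP3K7 fell by 0.80 (SE 0.10). TTI1 had -1.30 in T47D, -0.94 in MCF7 and -1.50 in MCF10A. The list's median was -0.11 (camera adjusted p = 2.03e-10, adjusted p = 0.202 with an estimated correlation). Among 28 histone genes 5 fell (14 adjusted over the list alone), led by H2BC9, H3C7 and H1-3, whose mean rested on the near absence of counts in MCF10A K700E, and the median was -0.46 (camera adjusted p = 7.91e-26, adjusted p = 0.257 with an estimated correlation). Of 13 mitochondrially encoded transcripts 7 rose (12 adjusted over the list alone), with MT-ND5 at 1.17 (SE 0.17) and MT-ND4 at 1.10 (SE 0.17) and a median of 0.68 (camera adjusted p = 3.04e-25, adjusted p = 0.202 with an estimated correlation).

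Amino acid stress genes included 4 of 25 that rose in the mean effect (12 adjusted over the list alone), among them the lipoprotein receptor VLDLR at 1.20 (SE 0.23), the mTOR regulator SESN2 at 0.84 (SE 0.16) and the gluconeogenic enzyme PCK2 at 0.86 (SE 0.18), with a median of 0.47 (camera adjusted p = 1.22e-11, adjusted p = 0.465 with an estimated correlation). Of 22 cholesterol synthesis genes 4 fell (8 adjusted over the list alone), including HMGCS1 at -0.54 (SE 0.10), LSS at -0.72 (SE 0.14) and HSD17B7 at -0.69 (SE 0.14), with a median of -0.27 (camera adjusted p = 4.31e-08, adjusted p = 0.202 with an estimated correlation). No interferon response gene was called of 27 over all genes and 3 rose adjusted over the list alone, with STAT2 at 0.49 (SE 0.13, edgeR adjusted p = 0.0846) and a median of 1.00 (camera adjusted p = 2.56e-11, adjusted p = 0.557 with an estimated correlation). IFIT1, of the same list, had 802 CPM in MCF7 K700E PreCre replicate 1 and 194 in MCF7 K700E replicate 2.

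MYC targets had 2 of 28 that fell in the mean K700E effect (2 adjusted over the list alone, median -0.19, camera adjusted p = 9.08e-05, adjusted p = 0.670 with an estimated correlation). NF-kappaB targets had 0 of 24 called (0 adjusted over the list alone, median 0.37, camera adjusted p = 0.00293, adjusted p = 0.620 with an estimated correlation) and p53 targets 0 of 23 (0 adjusted over the list alone, median 0.19, camera adjusted p = 0.00556, adjusted p = 0.648 with an estimated correlation). Unfolded protein response genes had 1 of 21 that fell (2 rose and 4 fell adjusted over the list alone, median -0.15, camera adjusted p = 0.00560, adjusted p = 0.703 with an estimated correlation). Nonsense-mediated decay factors had 2 of 17 that fell (2 adjusted over the list alone, median -0.08, camera adjusted p = 0.0181, adjusted p = 0.574 with an estimated correlation). Camera gave no call for U2 snRNP factors (1 of 22 rose, 1 adjusted over the list alone, median -0.07, adjusted p = 0.313), mesenchymal markers (1 rose and 1 fell of 21, the same numbers adjusted over the list alone, median -0.12, mean -0.0019 with a test direction of up, adjusted p = 0.647), serine and one-carbon genes (0 of 25 called, 3 rose and 3 fell adjusted over the list alone, median -0.02 with a test direction of up, adjusted p = 0.978) and haem and iron genes (1 of 25 fell, 2 rose and 2 fell adjusted over the list alone, median -0.0017 and mean -0.09 with a test direction of up, adjusted p = 0.982). No list call in any comparison held with an estimated correlation, where the lowest adjusted p was 0.135.

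**Figure D3:**
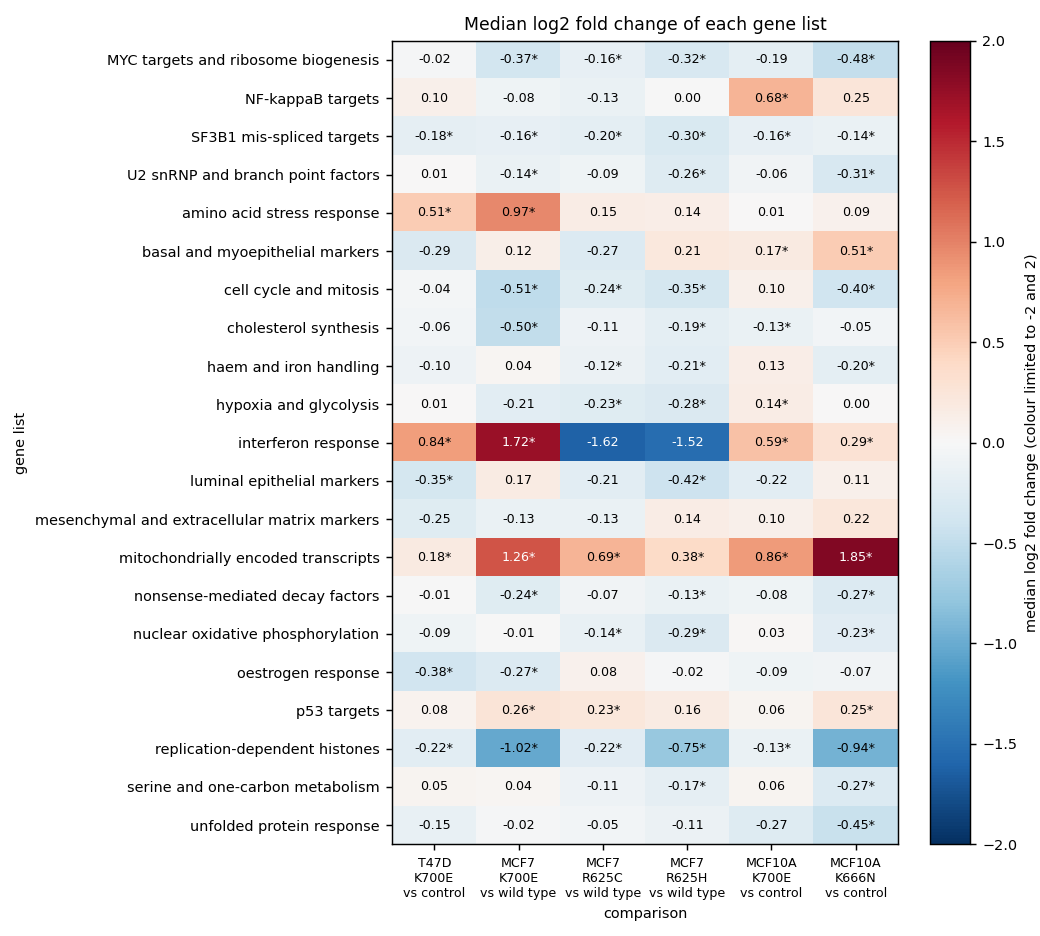
Median log2 fold change of each fixed gene list (y axis) in each comparison (x axis), with colour limited to values between -2 and 2 and * for a camera adjusted p under 0.05 with the preset correlation. The SF3B1 targets had a median of -0.18 in T47D K700E and -0.16 in MCF7 and MCF10A K700E, and the mitochondrially encoded transcripts 0.18, 1.26 and 0.86.

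edgeR called 418 of 28889 genes in the mean effect, 153 higher and 265 lower. The count was 224 without MCF10A K700E replicate 1, 222 without MCF10A K700E replicate 2, 274 without T47D PreCre replicate 1, 267 without T47D K700E replicate 1, 261 without T47D K700E replicate 3, 886 without the MCF10A PreCre library, 994 without the MCF10A parental library and 92 without T47D. TPP2 was the 1 gene called with the same sign in each line, at -0.68 in T47D, -1.31 in MCF7 and -1.95 in MCF10A (edgeR adjusted p = 0.00674, 0.0482 and 0.0467). It stood at 52.8 ± 1.43 CPM (SD, n = 4) in T47D K700E against 84.8 ± 11.5 (SD, n = 3) in controls. In MCF7 TPP2 less the median of its 20 Mb bin lay -0.77 from the PreCre clone of the same lineage in K700E replicate 1 and -0.18 in K700E replicate 2.

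The effect of K700E differed between lines for 419 genes by edgeR's quasi-likelihood test. The controls differed in kind, with PreCre libraries in T47D and MCF10A and reverted clones, without PreCre, in MCF7. In MCF7 alone edgeR called 2098 genes between PreCre clones and wild type. Differences of MCF7 from the other lines therefore cannot be told apart from those of control type. CHST1 had -5.87 in T47D and 2.98 in MCF7, and PRLR had -1.76 in T47D, 0.55 in MCF7 and 1.06 in MCF10A. PPOX had -1.05 in T47D, 0.43 in MCF7 and -0.90 in MCF10A, and HMGCS1 0.11, -0.34 and -1.41. The count was 253 without MCF10A K700E replicate 1, 260 without MCF10A K700E replicate 2, 2384 without the MCF10A parental library, 815 without MCF7 K700E replicate 2, 249 and 252 without T47D PreCre replicates 1 and 2, and 234 and 238 without T47D K700E replicates 1 and 3.

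Fold changes of K700E across genes, which are not independent replicates, had a Pearson r of 0.0231 between T47D and MCF7, 0.0432 between T47D and MCF10A and 0.0412 between MCF7 and MCF10A. In T47D and MCF7 41 genes were higher in both, where independent lists would share 20.2, 39 were lower in both against 16.01, and 57 went opposite ways against 39.7. For T47D and MCF10A 5 genes were lower in both against 1.39 in independent lists, 0 were higher in both and 3 went opposite ways against 1.17. For MCF7 and MCF10A 5 were lower in both against 0.331, 0 were higher in both and 1 went opposite ways against 0.597. These pairs share no control library. The MCF7 controls differed in kind from those of T47D and MCF10A, and an effect of that on the pairs with MCF7 was not tested.

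Within MCF7 the mutants share their wild-type libraries, so unchanged groups against the same controls were simulated. K700E and R625C had r = 0.378 (simulated 0.370) and a covariance of 0.102 (simulated 0.0364). For K700E and R625H r was 0.289 (simulated 0.327) with a covariance of 0.0753 (simulated 0.0371), and for R625C and R625H 0.517 (simulated 0.374) with a covariance of 0.107 (simulated 0.0368). With the wild-type libraries split so that no library was shared, the mean r was 0.190 (from -0.211 to 0.303), 0.112 (from -0.245 to 0.245) and 0.244 (from -0.05 to 0.432). Genes higher in both numbered 9 for K700E and R625C (0.422 in independent lists), 3 for K700E and R625H (0.187) and 1 for R625C and R625H (0.00576). Genes lower in both numbered 7 (0.298), 2 (0.246) and 0 (0.0175). Neither independent lists nor the simulated groups are a benchmark for these overlaps, since controls are shared and the simulated groups held no changed gene. All wild-type libraries were simulated with 1 mean, although reverted and unedited cells differed in 3218 genes. The simulated r and covariance need not hold here. With split controls R625C and R625H never both listed more than 1 gene. K700E and either R625 mutant did so in 1 of the 6 splits. That split set K700E against unedited cells and the R625 mutants against reverted clones, which come from the clone of K700E replicate 1. Changes of that clone enter both comparisons with opposite signs, which alone can give opposite genes and a negative r. For K700E and R625C 50 genes were higher in both (74.6 in independent lists), 59 lower in both (36.4) and 211 opposite (112.6). For K700E and R625H the numbers were 33 (63.7), 59 (31.1) and 189 (96.1). MCF10A K700E and K666N had r = 0.162 (simulated 0.549) with a covariance of 0.0612 (simulated 0.131). The MCF10A controls were not split, since each side would hold 1 library, and both values lay below the simulated ones.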

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

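The tests on the chromosome 6 genes, on chromosome 13, on TPP2 and of clone isolation, and the regroupings of T47D, R625C and PreCre libraries, were chosen after the results were seen, whereas the test of nuclear copies and the regroupings over the 3 lines were written before.

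In 7 of 110 groups of 4 or more libraries 1 library stood far from the others, where chance gives about 1 in 20. The gap to the nearest library, as a share of the range, was 0.917 for MUC1 in T47D K700E (replicate 1 highest). Among MCF7 wild-type libraries the parental library was highest in PLAGL1 (0.832), ZMAT3 (0.892) and ZNF716 (1.00) and lowest in CHAC1 (0.924), the unedited clone was lowest in LSS (0.832), and reverted replicate 1 had the highest total count (0.845).

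The K700E effect differed between the 3 lines for 21 of 77 named genes by edgeR's interaction test. Many of these genes were named for large changes in 1 line of the same data, so a high share follows from that choice. Among all 28889 tested genes the share was 1.45%. Adjusted p was 2.09e-07 for H3C7 and MTARC2, 1.69e-07 for H2BC9, 1.01e-05 for H1-3, 0.000116 for ONECUT2, 0.000137 for CHDH, 0.000228 for WT1 and 0.000839 for EPHX4, where the effect was largest in MCF10A. It was 0.00353 for PRLR, 0.00451 for CUX2, 0.0181 for CHST1, 0.0226 for ETV5, 0.0227 for PPOX and 0.0355 for EPGN, where it was largest in T47D. For MCF7 it was 0.00153 for PLAGL1, 0.00184 for GPRIN3, 0.00501 for NEURL1, 0.0252 for ASTL, 0.0282 for DLX2 and 0.0489 for SPRY4. HMGCS1 had 0.0129, with its lowest value in MCF10A. Over all genes 419 differed between lines, and 2 of 100 splits, the real one included, gave as many, with 424 in the other. That other split kept the T47D groups and exchanged the K700E and control libraries of MCF10A as whole groups, so it kept the real grouping within those lines. The share of splits lies under 0.05, but this count stands less clearly apart than those that no other split reached. Nor do the splits separate cell line from kind of control, which differed in MCF7.

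Other counts were also set against regroupings of the same libraries. No other split reached the count of T47D K700E (2166 genes, highest other split 6, 1 of 35 splits as large). The same held for MCF7 PreCre (2098, highest other 873, 1 of 100) and for the mean K700E effect (418, highest other 117, 1 of 100). In T47D the share could not fall below 1 of 35. Splits that mix both sides add their difference to the spread, so few calls are expected there. The splits also treat libraries as independent, although T47D K700E clones share lineages. Both reverted libraries of MCF7 come from 1 clone, and the PreCre count was 20 without them. The shares therefore do not exclude chance differences between clones or lineages. None of the 60 splits that parted the reverted libraries called a gene in edgeR, and of the 40 that kept them together 1, the real one, reached 2098, so an effect of that clone on the PreCre count stays open. Chance was not excluded for R625C (41 genes, highest other 88, 3 of 35).

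The missing histone counts of MCF10A K700E were the first pattern weighed. A general fall of replication-dependent histone mRNA is argued against by the median of -0.046 over the other 23 measured histone genes. Loss of 1 stretch of chromosome 6 is a candidate explanation. The highest count of the 4 genes from H3C6 to H2BC9 was 2 in either K700E library. The flanking genes kept 93.3% and 101% of the mean of controls that themselves differed. Both K700E libraries lacked the stretch, so its loss may have been present in a cell from which both came, which the labels do not state. An effect of K700E in every line is argued against by T47D and MCF7 K700E, where the lowest change of H3C7, H1-3 and H2BC9 was -1.19 (H2BC9 in MCF7, SE 0.21), and an effect particular to MCF10A stays open as untested.

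Lower expression of distal chromosome 13 in MCF7 R625C was the second pattern, with TPP2 inside it. Over 57 genes beyond 80 Mb the R625C PreCre clones differed from unedited cells by a median of -0.997 (SD 0.708), while R625C clones differed from their own PreCre clones by 0.015 (SD 0.406). This is consistent with a segment carried by the clone lineages, which K700E replicate 2 (-0.86) and its PreCre clone (-1.01) also had and K700E replicate 1 (0.23) did not, and argues against an effect of the mutant allele on the segment. TPP2 less the median of its 20 Mb bin differed under K700E by -0.74 in T47D and -1.34 in MCF10A, and in MCF7 K700E replicate 1 by -0.77 from its own PreCre clone, which argues against segment dosage as the whole cause there, whereas K700E replicate 2 differed by -0.18 from its own PreCre clone, which is consistent with dosage in that clone. TPP2 less its bin was also -1.22, -0.68 and -0.39 in the R625C clones against -0.21 and -0.23 in their PreCre clones, and -0.64 to -0.60 in MCF10A K666N against -0.065 and 0.065 in controls, differences that were not tested.

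Higher mitochondrially encoded transcripts in MCF7 K700E were the third pattern. The PreCre clones, which were also isolated, had a median change of 0.077 against 1.26 in K700E. Both medians rest on a wild type that includes the reverted clones, with 0.717% and 0.708% of counts. The parental library and unedited clone had 1.39% and 1.58%, so clones without the mutation differed as well. K700E replicate 2, at 1.75%, lay near the unedited clone, so variation between clones stays open. The PreCre clones of the same lineages had less, at 1.39% for K700E replicate 1 and 1.28% for replicate 2. R625C replicates 1 and 2 had 1.97% and 1.87% against 1.37% in their PreCre clone, and replicate 3 had 1.42% against 1.30%. The R625H clones had 1.73% and 1.47% against 1.30%. Each MCF7 mutant therefore lay above the PreCre clone of its own lineage. Reads shared with nuclear copies are argued against by 276 annotated nuclear copies, which held at most 1.82% of the summed counts of the copies and the 13 mitochondrial genes in an MCF7 library. Ribosomal RNA depletion, RNA yield and growth state were not tested and stay open, as does an effect of the mutation.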

How the results depend on the processing

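All alternatives were planned except the counts without both reverted libraries, without K666N replicates 1 and 2, and without chromosome segments that stand apart, which were chosen after seeing the data. Over 161 named gene results, 2133 of 2792 values kept their direction and their side of the threshold, 599 lost the call, 32 gained it and 28 changed sign. Over 51 list results, 717 of 879 values kept both, 139 lost the call and 23 changed direction. Where a value changed, the cause was not tested. Counts of similar size need not hold the same genes. In T47D 1853 of the 3333 genes called against PreCre alone were among the 2166. For MCF7 K700E the 909 genes held 77 of the 221 called with the lineage block. They held 306 of the 1026 called against PreCre alone and 498 of the 1020 called against unedited cells alone. For R625C 8 of the 180 genes called against PreCre alone were among the 41. The block test pairs each mutant with the PreCre clones of its lineage. For MCF10A, PreCre against wild type and reverted against unedited no paired analysis was possible because the labels do not state the lineage of the MCF10A mutants, only 1 lineage is on both sides of PreCre against wild type and none on both sides of reverted against unedited, where replicate numbers only name libraries. For R625 against K700E and the effects over 3 lines a block was not run. Leaving out a library of a pair leaves a lone one, which is assumed to vary like the other groups. In MCF10A a 2-fold change was recovered for 1.49% of simulated genes for K700E and K666N against control and 0% for K666N against K700E, so few calls there say little.

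The T47D count of 2166 was 3369 against PreCre with the lineage block, 3333 against PreCre alone, 3441 with DESeq2, 1432 with limma on FPKM (pseudocount 0.1), 988 with a 2-fold threshold and 716 to 3327 without 1 library. The MCF7 K700E count of 909 was 221 with the block, 2791 against reverted clones alone, 474 against wild type and PreCre together, 1843 with DESeq2, 0 with only the groups compared, 484 at 2-fold and 402 to 2015 without 1 library. R625C, with 41, gave 0 with the block, 180 against PreCre, 0 against unedited cells, 11 against wild type and PreCre together, 767 with DESeq2, 27 with limma (0.1), 96 with no filter, 72 with only the groups compared, 0 without both reverted clones and 0 to 191 without 1 library. R625H, with 27, gave 2 with the block, 6 against PreCre, 0 against unedited cells, 0 against wild type and PreCre together, 433 with DESeq2, 48 with a 1 CPM filter, 41 with no filter, 4 with only the groups compared, 10 with RLE, 16 at 2-fold, 0 without both reverted clones and 0 to 184 without 1 library. PreCre, with 2098, gave 3587 with DESeq2, 586 at 2-fold, 20 without both reverted clones and 370 to 4470 without 1 library. R625 against K700E, with 778, gave 1772 with DESeq2, 116 with only the groups compared, 360 at 2-fold and 17 to 2019 without 1 library. Reverted against unedited, with 3218, gave 1979 and 1345 with limma (0.1 and 1), 1709 at 2-fold and 100 to 1935 without 1 library.

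MCF10A K700E, with 34, gave 281 with DESeq2, 12 and 14 with limma, 207 with no filter, 0 with only the groups compared and 0 to 33 without 1 library. K666N, with 0 in edgeR, 0 in limma and 856 at an unadjusted p under 0.05, gave 97 with DESeq2, 5 with a 1 CPM filter, 68 with no filter, 1 against the parental library and 0 to 2 without 1 library. K666N against K700E, with 76, gave 535 with DESeq2, 27 and 23 with limma, 412 with no filter, 9 without K666N replicates 1 and 2, and 4 to 145 without 1 library. The mean effect, with 418, gave 1197 with DESeq2, 204 at 2-fold, 92 without T47D and 222 to 994 without 1 library, and the effect by line, with 419, gave 1419 with DESeq2, 272 without MCF7, 69 without T47D and 234 to 2384 without 1 library. Without chromosome segments that stand apart every count run stayed within 1.5 times of its value, and the effect by line was not run. Bins counted as apart only at a median log2 difference of at least 0.4, which left out 0 calls in T47D and 2 of 27 in R625H. The R625H shifts on chromosome 14 (-0.285 and -0.308) and distal chromosome 2 (-0.30 and -0.31) lie below that cut. Of the 19 lower R625H genes 9 and 4 lie there, so the check cannot tell whether that count depends on segments. On log2 FPKM (pseudocounts 0.1 and 1) the median over the 14939 genes also tested by edgeR moved by 0.11 and 0.10 in R625C, 0.16 and 0.14 in R625H, 0.13 and 0.12 in R625 against K700E, 0.21 and 0.18 in PreCre and -0.23 and -0.20 in reverted clones.

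Values that changed sign were mostly those of uncalled genes. SF3B1 had -0.063 in T47D against the parental library, and in MCF7 K700E -0.021 without K700E replicate 1 (range without 1 library -0.021 to 0.22). In R625C it had 0.53 with the block, 0.45 against PreCre, 0.22 against wild type and PreCre together, 0.019 with a 1 CPM filter, 0.075 and 0.073 with limma, 0.0011 without the unedited clone and -0.066 to 0.020 without 1 library, highest without R625C replicate 2. In R625H it had 0.22 with the block and 0.16 against PreCre. In MCF10A it had -0.10 for K700E against the parental library and -0.098 to 0.80 without 1 library (lowest without the PreCre library), and 0.32 for K666N against PreCre and -0.58 to 0.32 without 1 library (highest without the parental library). In R625C the block and PreCre alone gave -0.34 and -0.56 for GABARAPL1, 0.17 and 0.21 for BUB1, 0.27 and 0.23 for H2BC5, and the block gave -0.10 for ZMAT3. In R625H they gave -0.11 and -0.37 for GABARAPL1, and PreCre alone 0.036 for TK1. H3C12 in K666N had 3.09 against PreCre and -4.56 to 3.09 without 1 library, highest without the parental library.

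List medians that changed sign or test direction included luminal markers in T47D (0.0068 against the parental library) and, in MCF7 K700E with the block, cell cycle genes (0.066) and SF3B1 targets (-0.075). In R625C the block and PreCre alone gave 0.26 and 0.29 for cell cycle genes, 0.22 and 0.15 for MYC targets and 0.53 and 0.56 for histones, wild type and PreCre together gave 0.039 for cell cycle genes and 0.12 for histones, and unedited cells gave 0.034 for MYC targets and 0.086 for histones. In R625H the block and PreCre alone gave 0.11 and 0.20 for cell cycle genes, 0.12 and 0.039 for MYC targets and 0.13 and 0.094 for oxidative phosphorylation. In MCF10A histones in K700E had 0.52 against PreCre and -0.61 to 0.63 without 1 library (highest without the parental library), and oxidative phosphorylation in K666N had 0.14 against PreCre and -0.56 to 0.15 without 1 library (highest without the parental library).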

Other observations

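The tests in this part, and the list of MAPK output genes, were chosen after the values of ETV5 and SPRY4 were seen.

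Chromosome segments moved as blocks in some clones. Relative to the parental library both MCF10A K700E libraries had a median of -0.89 over the first 20 Mb of chromosome 5. Over the next 20 Mb it was -0.77 and -0.73, and beyond 80 Mb of chromosome 13 -0.60 to -0.47. There MCF7 R625C clones had -1.04 to -0.94, R625H clones -0.04 and 0.01 and reverted clones 0.43 and 0.37. MCF7 K700E replicate 1 had -0.99 to -0.42 in all bins of chromosome 5. Reverted clones had 12 bins apart from unedited cells, with 310 of 3218 calls.

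The interferon-stimulated gene IFIT1 had 802 CPM in MCF7 K700E PreCre replicate 1, 194 in MCF7 K700E replicate 2 and 39.1 in reverted replicate 1, and at most 6.05 in every other MCF7 library.

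Higher output of the MAPK pathway was examined as a hypothesis for the high ETV5 and SPRY4 in T47D and MCF7 K700E cells. In MCF10A K700E these genes had 0.32 and -0.053. Of 10 transcriptional targets of the pathway 6 rose and 1 fell in T47D K700E, with ETV4 at 2.38, EPHA2 at 1.34, DUSP6 at 1.29, SPRY2 at 1.04 and DUSP4 at -1.05, and 3 rose in MCF7 K700E, where DUSP4 had 3.28. Camera with an estimated correlation gave p = 0.00251 in T47D and 0.0348 in MCF7. Without ETV5 and SPRY4, which prompted the list, the other 8 genes gave 0.0257 in T47D and 0.151 in MCF7, so the hypothesis stays open in MCF7. The 10 genes gave 0.674 in MCF10A K700E (0.464 for the 8 others), 0.782 in K666N (0.659), 0.114 in R625C (0.280) and 0.0244 in R625H (0.0596), and 0.000338 in the mean K700E effect (0.0141).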
